A study of Mus musculus with 9 samples.

How the data were processed

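RNA was measured on 9 one-colour Illumina bead arrays of mouse epiblast stem cells, pluripotent cells with the properties of the epiblast after implantation. The cells were male and carried a dsRed2 fluorescent reporter. Per the labels, the medium held bFGF at 10 ng/ml and activin A at 20 ng/ml. The 3 groups of 3 biological replicates were cells sorted as dsRed2 positive, cells sorted as dsRed2 negative, and cells treated with 3 µM CHIRON for 48 h. The labels give only the name CHIRON; the name is commonly used for CHIR99021, an inhibitor of the kinase GSK3 that activates Wnt/β-catenin signalling. The labels do not settle whether the treated cells were sorted, so treatment and sorting cannot be separated in the comparisons with treated cells. The labels do not name the element that drives dsRed2, and no dsRed2 probe was analysed here.

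The deposited signal intensity is the mean bead signal per probe and array on a linear scale, not normalized, per the file headers. The detection p-value of each probe on each array was also taken as deposited, per the file headers. The deposited log2 values were normalized between arrays by the authors, with lumi per the submitters' processing notes; its version, transform and normalization method are not given in the sources used here. Per the labels, RNA was extracted with RNeasy columns and amplified and biotin-labelled with a TotalPrep kit. In those deposited values the column medians lay between 6.09 and 6.10. Against log2 of the signal of the same array they had slopes of 1.03 to 1.10, which fits a log2 scale with unchanged direction. Each deposited column correlated best, after centring of genes, with its own array.

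Signals of 45281 probes were background-corrected by normexp with parameters inferred from the detection p-values, given an offset of 16, quantile-normalized and log2-transformed (neqc of limma 3.58.1 in R 4.3.3). Probes with a detection p-value below 0.05 on at least 3 of the 9 arrays were kept, which left 19074. Gene names are those of the signal table, brought up to date through a table of current symbols. Of 30869 distinct symbols, 16219 were current, 5709 were updated through an unambiguous synonym and 8941 were kept as given; 22 symbols in the file have the form of dates. Each gene was represented by its passing probe with the highest mean, giving 13204 genes, of which 4129 had more than 1 passing probe. Between 0 and 79 genes per comparison had probes called in opposite directions. For a gene detected on no array of the dimmer group, the fold is given as a lower bound. It sets the mean of the brighter group against the mean, per dim array, of the higher of the lowest detected signal and the probe's own signal. A gene detected on some arrays of the dimmer group keeps its log2 difference, and the size of that difference then rests in part on values near background.

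The model was limma's lmFit and eBayes on all 9 arrays, with group as the only term, two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. Gene lists, 32 in number, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 32 lists. Errors of log2 differences are standard errors from the model, with n = 3 arrays per group unless stated. The groups, tests, lists, the rule for named genes and most alternatives were set before the data were examined. The rule took the 8 largest rises and falls per comparison among called genes whose groups did not overlap, leaving out unnamed gene models. It also took up to 4 members with the smallest p per list and comparison, and 12 key genes (T, Mixl1, Eomes, Foxa2, Axin2, Lef1, Sp5, Cdx2, Tbx6, Pou5f1, Sox2 and Nanog), all of which were tested. Genes called in both comparisons with dsRed2 negative cells, or raised or lowered stepwise, would have been added, but there were none. Genes outside the rule are named as chosen after their values were seen.

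The replicate numbers paired the sorted samples, on the evidence of the data: deviations from the group mean correlated across genes at r = 0.54, 0.58 and 0.35 between positive and negative arrays of the same number. With treated arrays of the same number the correlations ranged from −0.14 to 0.10, so no pairing of the treated arrays by number was seen. Treated replicates 1 and 2 correlated alike with negative replicate 1 (0.10 and 0.12) and with negative replicate 2 (−0.14 and −0.14). The check could therefore not tell their numbers apart, and a pairing is not excluded. The pairing was decided on these correlations, and a paired fit of the 6 sorted arrays is given beside the sort. Treated replicates 1 and 2 were closer to each other than any other pair compared: over 1559 bright genes the SD of their log2 difference was 0.123, against 0.139, 0.166 and 0.156 for same-numbered sorted pairs and 0.337 and 0.345 against treated replicate 3. No measure of array noise is at hand to say whether they are separate cultures or a repeated measurement, so they were kept as 2 samples and averaged as 1 in an alternative.

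The procedure was tested on simulated data for 13204 genes with 200 genes changed per fold size. For positive against negative cells, the 9-array fit recovered 0% of genes changed 1.5-fold, 95% of those changed 2-fold and 99.5% of those changed 4-fold, with 0, 15 and 6 false calls. The paired fit recovered 91.5%, 100% and 100%, with 10, 21 and 17 false calls. For treated against negative cells the recovery was 4%, 90.5% and 99% (1, 17 and 10 false calls), and for treated against positive cells 7%, 89.5% and 100% (4, 7 and 16 false calls). For lists only the comparison of the sorts was simulated: a list of 12 genes shifted by 0.3 was called in 20 of 20 draws, with 2 false list calls in all. Simulated noise was independent between genes and, outside the paired fit, between arrays. Real list members vary together, with an estimated correlation of 0.81 for the G2/M list. The simulation therefore does not give the power or the false calls for such lists.

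Alternatives changed the background correction, the normalization, the source of the values, the filter, the handling of several probes per gene, the replicate block, the samples in the fit, the variance model and array weights, and left out each array in turn. The precision of array values is limited by the number of arrays.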

Results

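Expression was profiled on 9 arrays, 3 each of dsRed2 positive, dsRed2 negative and CHIRON-treated epiblast stem cells. Median probe signals lay between 95.1 and 109, and 36.7% to 41.1% of probes were detected per array. The title of the series concerns Wnt signalling and an epiblast stem cell subpopulation that resembles the primitive streak, the site where mesoderm and endoderm form in the gastrulating embryo. The comparisons therefore ask how reporter-positive cells differ from reporter-negative cells, and how either sort differs from cells after 48 h of CHIRON. The first principal component held 75.2% of the variance and placed the treated arrays apart from the sorted arrays, and component 2 held 7.8%.

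**Figure D1:**
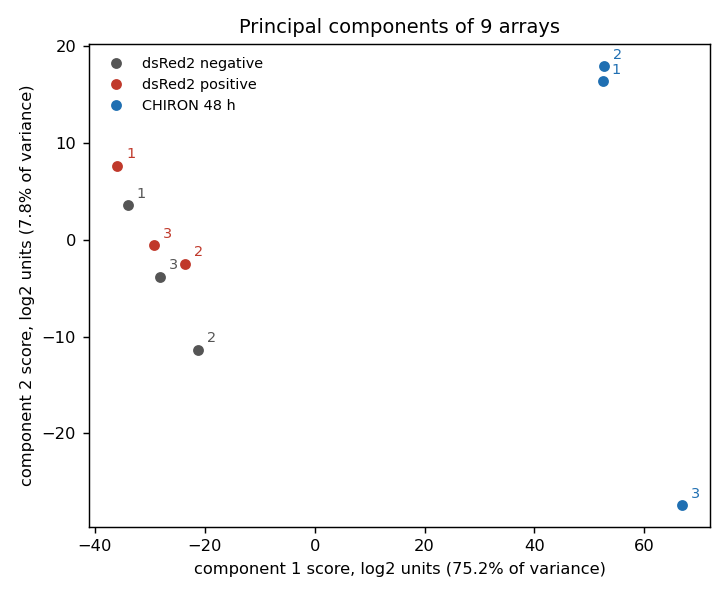
Scores of the 9 arrays on principal components 1 and 2 (log2 units), with the replicate number beside each point and colour for the group. Component 1 (75.2% of variance) parts treated from sorted arrays, and treated replicate 3 lies at −27.39 on component 2, against 16.41 and 17.95 for treated replicates 1 and 2.

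In dsRed2 positive against dsRed2 negative cells, most differences were small, with a median absolute log2 difference of 0.09. Of 18 primitive streak genes, 12 had the higher mean in positive cells (median 0.06; camera adjusted p = 0.349): T, the brachyury transcription factor of nascent mesoderm, by 0.65 ± 0.49 (log2), Fgf8, a growth factor of the streak, by 0.73 ± 0.45, Gsc, the homeobox factor of the anterior streak, by 0.61 ± 0.27, and Eomes, a T-box factor of mesendoderm, by 0.38 ± 0.19. Of 17 epithelial genes 6 had the higher mean (median −0.05; camera adjusted p = 0.215), and the keratin gene Krt8 differed by −0.67 ± 0.23 and Cldn4, which encodes a tight junction protein, by −0.63 ± 0.12. The pluripotency factors Nanog and Pou5f1 differed by 0.00 ± 0.20 and −0.03 ± 0.29. Second passing probes differed by 0.32 for Nanog, −0.05 for Pou5f1 and −0.01 for Eomes. None of these passed over all genes in the 9-array fit, which leaves the pairing of the sorts out: limma called 0 of 13204 genes, with 370 at an unadjusted p below 0.05 against 660 expected by chance, and a lowest adjusted p of 0.9998. Groups did not overlap for 1013 genes (7.67%), where chance gives 10% for 3 arrays against 3 if the 6 arrays are exchangeable, which the pairing of the sorts contradicts. In pairs, 2050 genes were higher and 1985 lower in all 3, where chance gives 12.5% of 13204 each, or 1650. An exact test of 3 against 3 cannot go below p = 0.1.

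With same-numbered positive and negative arrays paired, a fit of the 6 sorted arrays chosen after seeing the data called 3 genes, all lower in positive cells in 3 of 3 pairs. They were Tmem223, a transmembrane protein gene, by −1.68 (adjusted p = 0.0057), Prxl2a, a peroxiredoxin-like gene, by −1.46 (adjusted p = 0.0057), and Eif2s3y, a translation initiation factor gene on the Y chromosome, by −1.58 (adjusted p = 0.0078). The same fit on the deposited values called 43 genes, 3 higher and 40 lower, with Prxl2a at −0.61, Eif2s3y at −0.69 and Tmem223 at −1.43. Among the 43 were Trh (0.60, adjusted p = 0.00485) and Gdf3 (0.45, adjusted p = 0.0272), both higher, and Krt8 (−0.66, adjusted p = 0.0147), Tfap2c (−0.44, adjusted p = 0.0254), Cldn4 (−0.46, adjusted p = 0.0336), Col4a1 (−0.39, adjusted p = 0.0371), Bgn (−0.52, adjusted p = 0.0430) and Dppa4 (−0.34, adjusted p = 0.0434), all lower. With treated arrays in the fit but outside the block, the call of Prxl2a was lost (adjusted p = 0.305). Eif2s3y on positive replicates 1 and 2 and Prxl2a on positive replicate 2 lay below the lowest detected signal of their arrays, so the sizes of these falls depend on the background correction. These 3 lie outside the naming rule and were chosen after their values were seen. At an unadjusted p below 0.05 the paired fit had 1210 genes. The planned block on replicate number over all 9 arrays called 0 genes, with 475 at an unadjusted p below 0.05.

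In the paired fit 5 of the 18 primitive streak genes tested were higher in positive cells when adjusted over the list alone, and 0 when adjusted over all genes. They were T (adjusted p over the list = 0.0225), Fgf8, Gsc, Fst, which encodes the activin antagonist follistatin (0.39), and Eomes, each higher in 3 of 3 pairs. A second passing Eomes probe had a mean difference of −0.01. Eomes was detected on 0 negative arrays and Gsc on 1, so their sizes rest in part on values near background. The sizes for T and Fgf8 rest most on pair 3: the pair differences were 0.50, 0.27 and 1.17 for T and 0.28, 0.68 and 1.25 for Fgf8. The list as a whole was higher by camera (adjusted p = 0.032), and the adjusted p was 0.593 with an estimated correlation. Axin2, a feedback gene of Wnt/β-catenin signalling, had a mean difference of 0.33 and was higher in 3 of 3 pairs, but 0 of the 16 Wnt targets passed over the list alone. Trh, the thyrotropin-releasing hormone gene, was the 1 of 15 anterior streak, endoderm and axial mesoderm genes higher over the list alone (0.94, adjusted p over the list = 0.00121), and 0 passed over all genes in this fit. Among 12 core pluripotency genes, Gdf3, a TGF-β family ligand, was higher (0.52) and Dppa4 lower (−0.40) over the list alone.

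Other lists were lower in positive cells in the paired fit. Of 7 fibroblast and feeder genes, 4 were lower over the list alone: the smooth muscle actin gene Acta2 (−0.91, with −0.44, −1.56 and −0.73 in the pairs), the proteoglycan gene Bgn (−0.80) and the collagen genes Col1a1 (−0.59) and Col6a1 (−0.53). Of 9 visceral and parietal endoderm genes, 3 were lower over the list alone (Col4a2 at −0.65, Dab2 at −0.37 and Sparc at −0.37), and of 15 mesenchymal transition genes 1 was (Col4a1 at −0.60). A second passing Dab2 probe differed by only −0.03, and a second Sparc probe by −0.30. By camera these lists were lower with adjusted p = 0.00426 (fibroblast and feeder), 0.00937 (endoderm) and 0.00426 (mesenchymal transition), and the p53 response list was lower with adjusted p = 0.0307 and 0 of its 11 members past the test over the list alone. For all 4 the adjusted p was 0.593 with an estimated correlation, and fry called 0 of 32 lists. Krt8 and Cldn4 were lower over the list of 17 epithelial genes, Id3, a BMP-induced inhibitor of differentiation, over the list of 7 BMP targets, and Tfap2c, a factor of germ cell and trophoblast precursors, over the list of 3 germ cell genes. Over the lateral mesoderm list Bmp4 (−0.56) and Ets1 (−0.41) were lower and Etv2 (0.36) higher. Over the trophoblast list Tfap2c and Plac1 (−0.42) were lower and Eomes higher. Dppa5a (−0.42) was lower over the naive pluripotency list, and Ddit3 (−0.45) over the amino acid and ER stress list. In the 9-array fit camera called 0 of 32 lists, and 3 list members passed over a list alone, Cldn4, Id3 and Tfap2c.

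**Figure D2:**
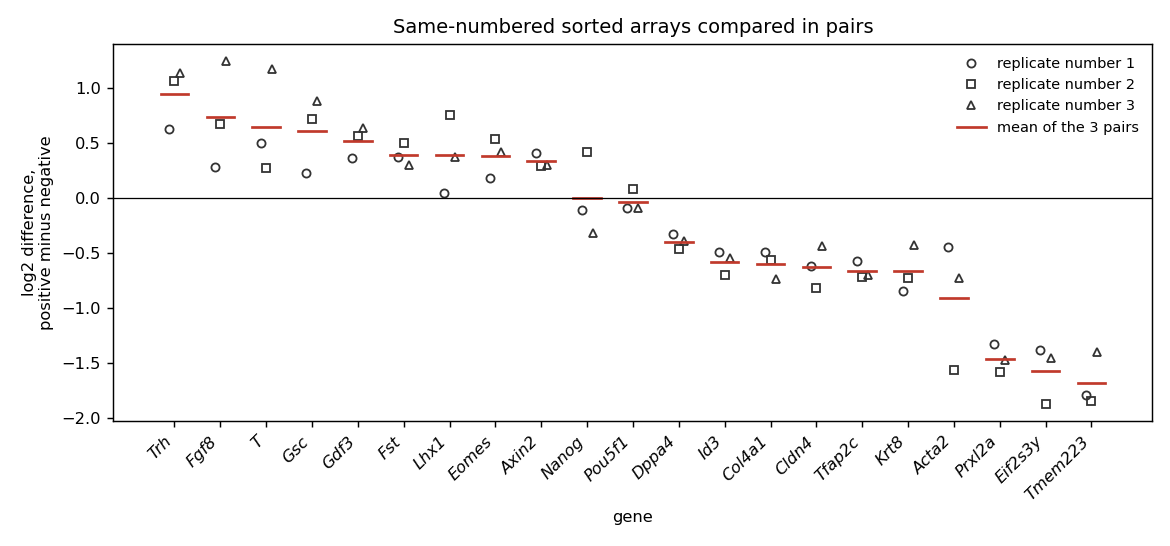
Log2 differences of positive minus negative arrays for 21 genes, with a symbol per replicate number and a line at the mean of the 3 pairs. Acta2 had the widest spread of pairs among the genes drawn, while Tmem223, Eif2s3y and Prxl2a were below −1.3 in all 3 pairs.

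After 48 h of CHIRON, genes of the streak and its derivatives rose far above the levels of dsRed2 negative cells. T rose by 5.66 ± 0.49, Gsc by 6.13 ± 0.27, Lhx1, an organizer homeobox gene, by 6.98 ± 0.28, and Mixl1, a homeobox gene of the streak that was detected on 0 negative arrays, at least 8.18-fold. Gsc and Lhx1 were detected on 1 and 2 of 3 negative arrays and their means there lay below the lowest detected signal, so the sizes of their rises are uncertain. The endoderm factors Sox17 and Foxa2 rose at least 29.5-fold and 6.88-fold, and Cdx2, a regulator of posterior identity, at least 10.6-fold. Pluripotency genes fell: Nanog by 3.46 ± 0.20, Pou5f1 by 1.84 ± 0.29 and Sox2 by 0.96 ± 0.13. In all, limma called 5280 of 13204 genes, 2651 higher and 2629 lower, of which 807 and 819 differed at least 2-fold. With treated replicates 1 and 2 averaged as 1 sample, an alternative chosen after seeing the data, 4465 genes were called. Scaling by the median of each array gave 2817 higher and 1282 lower genes, 68.7% higher against 50.2%, with a shift of 0.14 in the median of all genes.

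**Figure D3:**
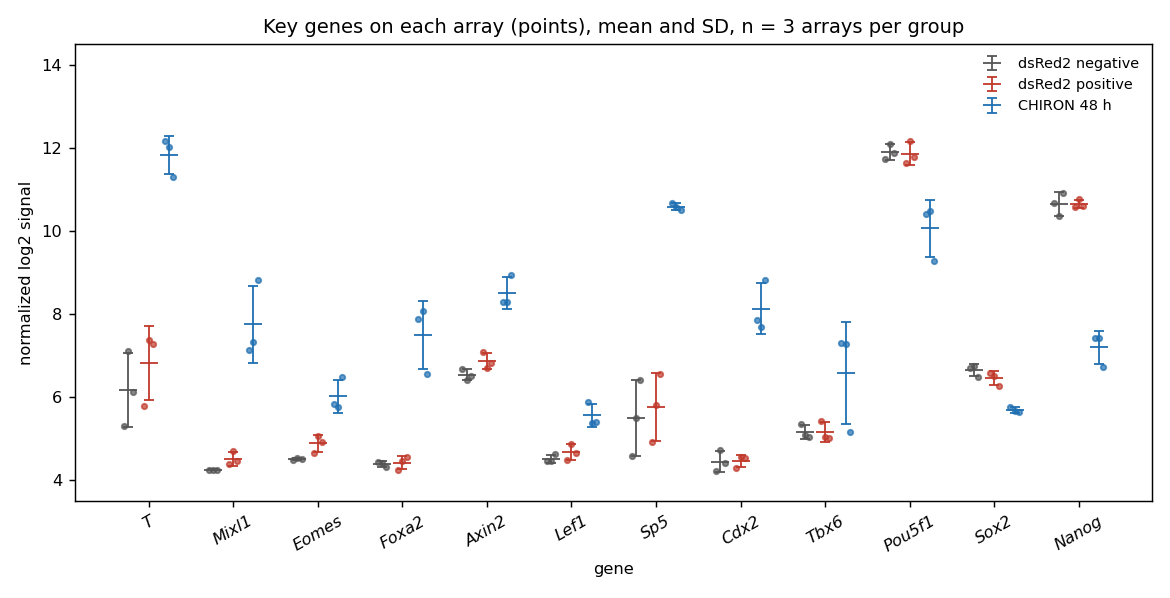
Normalized log2 signal of the 12 key genes on each array (points), with the mean and SD of 3 arrays per group. The treated arrays lie above both sorts for T and Sp5 and below them for Nanog, and Tbx6 varies most among the treated arrays.

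The gene with the largest fitted rise was Pga5, a pepsinogen gene detected on 0 negative arrays, at least 138-fold (adjusted p = 7.6e-11). Rises from near background are of uncertain size, so its rank is uncertain too. Spink1, a trypsin inhibitor gene, rose 128-fold from near background, where it was detected on 1 negative array, and Trh rose by 5.73 ± 0.60. Sp5, a direct Wnt target, rose by 5.08 ± 0.45, and Cyp26a1, a retinoic acid-degrading enzyme of the streak and tail bud, by 5.11 ± 0.21. The largest falls were of Rgcc, a cell cycle regulator gene, at −5.26 ± 0.37, of Dppa5a, which fell by 4.19, and of the amino acid transporter gene Slc7a3, which fell by 4.10. Ramp3 fell by 3.82, Apobec1 by 3.67 and Enpp2, which encodes autotaxin, by 3.43. Utf1, a chromatin factor gene of pluripotent cells, fell by 3.64.

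Of 16 Wnt targets tested, 11 rose and 0 fell, with Axin2 at 1.97, Dkk1, a Wnt antagonist detected on 1 negative array, at 3.46, Lef1 at least 1.79-fold and Lgr5 at least 2.22-fold (camera adjusted p = 7.65e-06; adjusted p = 0.104 with an estimated correlation). Of 18 primitive streak genes 13 rose, Snai1 by 2.63 and Eomes at least 2.46-fold among them, while Fgf17 fell by 1.75, Nodal by 0.87 and Tdgf1, the Nodal co-receptor gene, by 0.70 (adjusted p = 1.86e-05; adjusted p = 0.278 with an estimated correlation). The call of Tdgf1 was lost without negative replicate 3 (adjusted p = 0.0652) and with median centring (−0.47, adjusted p = 0.145), and its difference was −0.46 without treated replicate 3. Of 15 anterior streak, endoderm and axial mesoderm genes 13 rose, with Gata6 at least 24.0-fold, Foxa1 at least 19.5-fold and Shh, the notochord signal, at least 15.8-fold (adjusted p = 8.43e-10; adjusted p = 0.0946 with an estimated correlation). Of 12 posterior growth zone genes 11 rose, with Wnt5a at least 13.9-fold and Nkx1-2 at least 2.26-fold (adjusted p = 2.66e-08; adjusted p = 0.0946 with an estimated correlation). Of 13 Hox genes 8 rose and 0 fell, Hoxb2 by 1.25 and Hoxb1 at least 3.12-fold (adjusted p = 0.00285; adjusted p = 0.278 with an estimated correlation). The counts over each list alone were the same for these lists, except 9 Hox genes. The detection filter left 13 of 39 listed Hox genes. Genes detected on no sorted array pass it only through the treated arrays. The share that rose and the 0 that fell are therefore in part fixed by the filter.

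Mesoderm lists rose as well. Of 7 paraxial mesoderm genes 5 rose, Rspo3 by 3.48 and Foxc1, detected on 1 negative array, by 2.15, and Tcf15 fell by 1.54 (adjusted p = 0.00693; adjusted p = 0.278 with an estimated correlation). Tbx6, a factor of presomitic mesoderm, differed by 1.43 ± 0.46 (adjusted p = 0.030). Without either treated replicate 1 or 2 that call was lost (adjusted p = 0.111 in both), as it was without negative replicate 1, 2 or 3 (adjusted p = 0.0552, 0.0700 and 0.0813). It was also lost with no filter (adjusted p = 0.113) and with only the 6 arrays compared (adjusted p = 0.0554). Averaging treated replicates 1 and 2 lost it too (adjusted p = 0.111). Of 8 lateral mesoderm genes 4 rose, with Msx1 at least 10.1-fold and Isl1 at least 2.57-fold (adjusted p = 0.00984; adjusted p = 0.278 with an estimated correlation). Of 7 BMP targets 3 rose, with Id1 at 2.87 and Id3 at 2.44 (adjusted p = 0.00379; adjusted p = 0.337 with an estimated correlation). Of 15 mesenchymal transition genes 6 rose, with Col4a1 at 2.51 and Fn1, fibronectin, at 2.38 (adjusted p = 0.00449; adjusted p = 0.337 with an estimated correlation). That list call was lost without treated replicate 3 (adjusted p = 0.0826). Of 7 trophoblast markers 6 rose, with the keratin gene Krt7 at 2.16, and Cdx2 and Eomes also belong to that list (adjusted p = 0.00154; adjusted p = 0.249 with an estimated correlation). Of 3 germ cell markers 2 rose, the receptor gene Kit by 4.16 (adjusted p = 0.0219; adjusted p = 0.278 with an estimated correlation), a list call lost with no filter (adjusted p = 0.0579). Over each list alone 6 paraxial, 5 lateral, 5 BMP, 6 mesenchymal, 6 trophoblast and 2 germ cell genes rose. The detection filter left 7 of 15 listed paraxial, 8 of 15 lateral, 7 of 13 BMP, 7 of 12 trophoblast and 3 of 11 germ cell genes. The shares that rose are in part fixed by it, as for the Hox genes.

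Of 12 core pluripotency genes 9 fell and Sall4 rose by 1.06; Gdf3 fell by 3.40 and Dppa4 by 2.24 (camera adjusted p = 6.4e-04; adjusted p = 0.278 with an estimated correlation). All 12 G2/M genes tested fell, the proliferation marker Mki67 by 1.39, Aurkb by 1.23 and Cdc20 by 0.87 (adjusted p = 1.98e-05; adjusted p = 0.337 with an estimated correlation), while 2 of 15 S phase genes rose and 2 fell. Of 12 amino acid and ER stress genes 8 fell and 1 rose: Ddit3 fell by 1.83, and Asns, which encodes asparagine synthetase, fell by 1.36 (adjusted p = 0.00984; adjusted p = 0.289 with an estimated correlation). Of 15 glycolysis and hypoxia genes 7 fell, and Pdk1 fell by 1.75 (adjusted p = 0.0323; adjusted p = 0.589 with an estimated correlation). The glycolysis call was lost without negative replicate 2 (adjusted p = 0.0672) or treated replicate 3 (adjusted p = 0.161), and with array weights (adjusted p = 0.154). Of 12 immediate early genes 6 fell and 1 rose: Zfp36 fell by 1.81, Atf3 fell by 1.54 and Ccn2 fell by 2.89 (adjusted p = 0.0493; adjusted p = 0.562 with an estimated correlation). Ccn2 was at 9.50, 9.35 and 12.1 on treated replicates 1, 2 and 3, against 13.3, 13.1 and 13.3 on the negative arrays. The size of its fall therefore rests most on treated replicates 1 and 2. The immediate early call was lost without negative replicate 1 or 2, positive replicate 2 or 3, or treated replicate 1 or 2 (adjusted p = 0.0613, 0.0767, 0.0544, 0.0512, 0.121 and 0.0937). It was also lost with no background correction (adjusted p = 0.0706), with the deposited values (adjusted p = 0.0699) and with the mean of probes (adjusted p = 0.0516). Fos fell by 2.38 ± 0.64, a call lost without negative replicate 1 (adjusted p = 0.0508), with no filter (adjusted p = 0.0613), with no background correction (−1.40, adjusted p = 0.0653) and with the deposited values (−1.42, adjusted p = 0.0712). Over each list alone the same numbers rose and fell in these lists, except 1 S phase gene that fell.

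**Figure D4:**
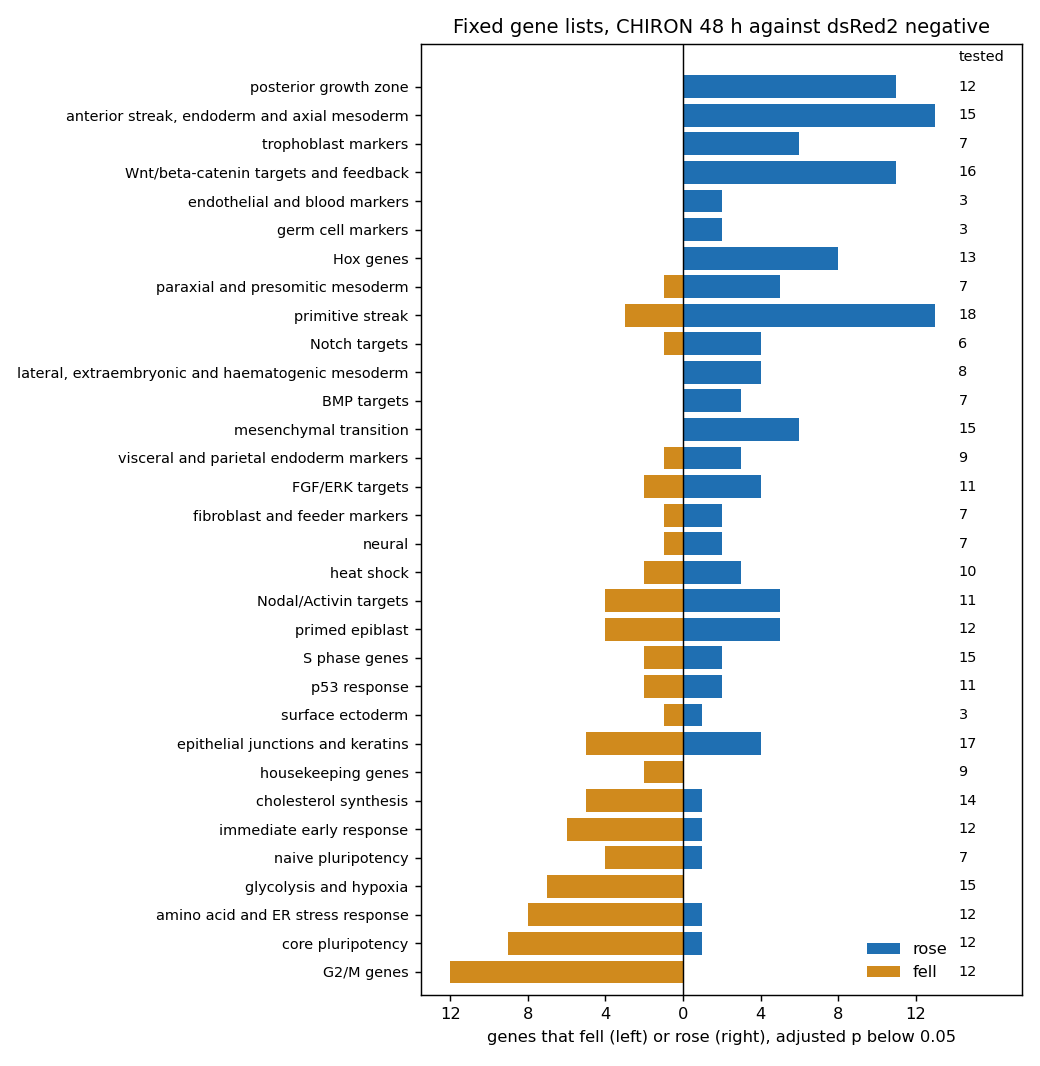
Number of genes in each of the 32 lists that rose (right) or fell (left) in CHIRON-treated against dsRed2 negative cells at an adjusted p below 0.05, with the number tested at the right. All 12 tested G2/M genes lie on the falling side, and 13 of 15 anterior streak, endoderm and axial mesoderm genes on the rising side.

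By camera 16 of 32 lists were called against negative cells, 11 higher and 5 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.0946), and fry called 22. Fry asks whether list members differ at all, not whether they differ more than other genes, and 5280 of 13204 genes were called. The housekeeping list passed fry (adjusted p = 0.00142) but not camera (adjusted p = 0.318). The counts by fry, here and against positive cells, are therefore not comparable with those by camera.

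The comparison with dsRed2 positive cells shares the treated arrays with that against negative cells. T rose by 5.02 ± 0.49, Gsc by 5.51 ± 0.27, Lhx1 by 6.59 ± 0.28, Axin2 by 1.63 ± 0.19 and Sp5 by 4.82 ± 0.45. Mixl1 rose at least 8.15-fold, Foxa2 at least 6.86-fold, Sox17 at least 29.4-fold and Cdx2 at least 10.6-fold, all detected on 0 positive arrays. Eomes rose by 1.13 and Lef1 by 0.89. Tbx6 differed by 1.42 (adjusted p = 0.030), a call lost without positive replicate 2 or 3 (adjusted p = 0.0739 and 0.0844) and without treated replicate 1 or 2 (adjusted p = 0.112 and 0.111); without treated replicate 3 the difference was 2.13. The Tbx6 call was also lost with no filter (adjusted p = 0.113), with only the 6 arrays compared (adjusted p = 0.0559) and with treated replicates 1 and 2 averaged (adjusted p = 0.112). Nanog fell by 3.45, Pou5f1 by 1.80, Sox2 by 0.76 and Gdf3 by 3.92. Pga5 rose at least 137-fold; Rgcc fell by 5.57, and Slc7a3 by 4.18. Limma called 5420 genes, 2711 higher and 2709 lower, of which 848 and 841 differed at least 2-fold; with treated replicates 1 and 2 averaged 4674 were called, and scaling by array medians gave 2719 higher and 1417 lower (65.7% higher), with a shift of 0.12 in the median of all genes.

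By camera 17 of 32 lists were called against positive cells, 12 higher and 5 lower, 0 with an estimated correlation (lowest adjusted p = 0.108) and 22 by fry. The list called here alone was that of visceral and parietal endoderm markers, in which 5 of 9 genes rose, among them Col4a2 by 3.00 and Apoa1, an apolipoprotein gene detected on 0 positive arrays, at least 8.99-fold (adjusted p = 0.0109; adjusted p = 0.170 with an estimated correlation). The difference of that list between the comparisons is its difference between the sorts, which was not called over the 9 arrays (adjusted p = 0.105) and was called in the paired fit (adjusted p = 0.00937; adjusted p = 0.593 with an estimated correlation). Of 17 epithelial genes 6 rose and 3 fell against positive cells, Krt8 by 2.05 and Cldn4 by 0.78, the latter 0.15 ± 0.12 against negative cells. All 12 G2/M genes fell (adjusted p = 1.76e-05; adjusted p = 0.339 with an estimated correlation). The immediate early list, with 7 of 12 genes lower, was called (adjusted p = 0.0276; adjusted p = 0.504 with an estimated correlation), but not without treated replicate 1 or 2 (adjusted p = 0.0816 and 0.0605). The glycolysis and hypoxia list, with 7 of 15 genes lower, was called (adjusted p = 0.0196; adjusted p = 0.547 with an estimated correlation), but not without treated replicate 3 (adjusted p = 0.0977) or with array weights (adjusted p = 0.0951).

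The comparison of the sorts and the comparison of treated with negative cells share the negative arrays. Across 13204 genes, which are not independent replicates, their log2 differences correlated at r = 0.025, where unchanged groups gave 0.499 when simulated as 9 independent arrays and 0.324 when simulated with the sorts paired. The covariance was 0.00305, against simulated values of 0.0162 and 0.00680. The same sign was found for 54.0% of genes, against 66.7% and 61.7% simulated. The simulated treated arrays carried no change, and the real ones did. A wider spread of the treated differences alone shrinks r and the share of equal signs. Those measures therefore cannot be set against their simulated values, here or against positive cells. The covariance is not scaled by that spread. Genes called in the same direction in both comparisons numbered 0, since limma called 0 genes between the sorts. With treated against positive cells, which share the positive arrays, the correlation was −0.190 (simulated −0.501 and −0.323) and the covariance −0.0236 (simulated −0.0163 and −0.00678). The difference between positive and negative cells was also set against treated cells minus the mean of both sorts, a quantity free of that shared term and added after seeing the data. Its correlation was −0.084 and its covariance −0.0103, with simulated means of 3.21e-04 and 6.36e-06 for paired sorts.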

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

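All tests in this part were chosen only after the results they concern were seen.

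The 6 arrays of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. Against negative cells the real split called 5280 genes, the highest of the other splits 0, and 1 split of 10 gave as many. Against positive cells the real split called 5420 genes, the highest other 0, and again 1 split gave as many. In both comparisons every other split puts treated arrays on both sides, so the treatment difference adds to the spread. Those splits had at most 499 and 547 genes at an unadjusted p below 0.05, against 660 expected by chance. Their 0 calls were therefore largely fixed in advance and decide nothing. Between positive and negative cells all 10 splits called 0 genes. In the paired fit, where the comparison is with the 3 other splits that part all 3 pairs, the real split called 3 genes and each of the others 0, with 1210 genes at an unadjusted p below 0.05 against at most 662. The 6 splits that part 1 pair each put a same-numbered pair on the same side; the highest of them had 1495 genes at an unadjusted p below 0.05 in the 9-array fit, against 370 for the real split.

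Genes brighter on treated replicate 3 than on treated replicates 1 and 2 had lower means in positive than in negative cells. For the top 200 such genes, ranked on treated arrays alone, the median difference between the sorts was −0.15, with −0.11, −0.28 and −0.12 in the 3 pairs. Genes that vary together can shift together over 3 pairs, so no chance range is given. Normalization as the whole cause is argued against: over 3 other ways of processing the highest median was −0.0657, and the median was below 0 in all 3 pairs in each. The size depends on the background correction, since without it the median was −0.0657, with the deposited values −0.0665 and with median centring −0.138. A large share of fibroblast feeder cells in the negative sort is argued against by 8 of 15 fibroblast markers that were detected on 0 negative arrays, Col1a2, Col3a1 and Dcn among them. Acta2, Bgn, Col1a1, Col6a1, Thy1 and Fbn1 were detected on all 3 negative arrays and Tagln on 2. In the paired fit Acta2 (−0.91), Bgn (−0.80), Col1a1 (−0.59) and Col6a1 (−0.53) were lower in positive cells over their list alone. Thy1, Fbn1 and Tagln did not pass. A small share of feeder cells is therefore not excluded. A share of spontaneously differentiating cells in the negative sort and in treated replicate 3 may account for the pattern, and was not tested.

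Tmem223, Prxl2a, Eif2s3y and Ddx3y were lower in positive than in negative cells in all 3 pairs. Noise of a single Tmem223 probe is argued against, since its second probe had a smallest fall of −1.40 among the pairs; the second Prxl2a probe was dim and gave 0.03, −0.59 and −0.97. A share of cells without the Y chromosome could lower Eif2s3y and Ddx3y, and stays open: 2 of 3 tested Y-linked genes were lower in all pairs, and the other, Uty, lay near background, so too few genes decide. Tmem223 and Prxl2a are not Y-linked, but their smallest fall of −1.33 decides nothing, because they were chosen for these falls. Tmem223 rose with the Y-linked genes over negative replicates 1, 2 and 3 (8.91, 9.50 and 10.7, beside 6.32, 7.24 and 8.60 for Ddx3y and 6.03, 6.44 and 7.77 for Eif2s3y). Prxl2a, at 6.50, 6.17 and 6.99, did not rise steadily over them. A subclone that differs in Tmem223, Ddx3y and Eif2s3y stays open and was not tested. The treated arrays were above every negative array for Prxl2a (10.2, 10.2 and 9.40 against at most 6.99), Ddx3y (9.18, 9.19 and 9.21 against at most 8.60) and Eif2s3y (at least 7.80 against at most 7.77), so the level of these genes varied beyond the sort. Apart from the share of cells without the Y chromosome, which stays open, no biological explanation was tested.

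Of 12 immediate early genes 6 fell, 1 rose and 5 did not pass in treated against negative cells, and 7 fell, 1 rose and 4 did not pass against positive cells, with list medians of −0.87 and −1.25. The list was called at the preset correlation, but the adjusted p was 0.562 and 0.504 with an estimated correlation, and the call was lost without treated replicate 1 or 2 (adjusted p = 0.121 and 0.0937 against negative cells, 0.0816 and 0.0605 against positive cells) and, against negative cells, without each of 4 other arrays. Handling of the cells during sorting could raise these genes in both sorts, but the labels do not settle whether treated cells were sorted, so the treatment and the handling cannot be told apart. The highest of the list's medians was −0.87, while the heat shock list, also responsive to handling, had medians of −0.01 and −0.02. An effect of CHIRON itself stays open and was not tested separately.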

How the results depend on the processing

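The paired fits of the sorts and the averaging of treated replicates 1 and 2 were chosen after seeing the data; the other alternatives were planned, and a block on slide was not run because no column or header gives a slide. Against negative cells the count of called genes stayed within 1.5 times of 5280 in every alternative that counts genes (4099 with array medians to 6030 with array weights; 4265 to 5194 without 1 array), and against positive cells of 5420 (4136 to 6690; 4336 to 5423). The count of lower genes alone moved by more than 1.5 times with array medians in both comparisons, as given above. With every probe tested singly, 7506 and 7657 of 19074 probes were called. The replicate block gave 5578 and 5761. Between the sorts all settings fixed in advance called 0 genes, the replicate block over 9 arrays included. The added fits called 3 (block on the 6 sorted arrays), 2 (block on the sorts with treated arrays outside it) and 43 (deposited values, block on the 6 sorted arrays; 3 higher and 40 lower); the cause of the higher count was not tested. Genes called in the same direction in both comparisons with negative cells stayed at 0 wherever they were counted. Each of those settings called 0 genes between the sorts, which fixes that count. The overlap was not counted for the added fits. Among the 43 genes, Trh, Dppa4, Dppa5a and Ddit3 moved the same way after CHIRON against negative cells. Gdf3, Krt8, Col4a1, Tfap2c, Cdkn1a, Prxl2a, Eif2s3y and Ddx3y moved the opposite way. These are examples, and the directions were not counted over all 43 genes. Lists between the sorts went from 0 to 3 with median centring, 1 with the deposited values, 2 with the stricter filter, 4 with only the 6 arrays and 5 with the block on them. Leaving out 1 array gave 0 to 4: 1 without negative replicate 3, 4 without positive replicate 1 (3 higher, the primitive streak among them) and 4 lower without treated replicate 3; apart from fewer samples, the cause was not tested. Lists against negative cells went from 16 to 0 with an estimated correlation (14 to 17 without 1 array) and against positive cells from 17 to 0 (16 to 18 without 1 array, 20 with no filter). Between the sorts, where none was called, 15 to 20 of 120 genes followed changed sign without 1 sorted array. The reversals were of other probes of a gene tested singly: Pdgfra against positive cells (−0.14), Ccng1 (0.94 against negative and 1.04 against positive cells) and Cenpf against negative cells (0.01); the cause was not tested. The block over 9 arrays changed the call of no list. Signal close to background limits the dim genes: those detected on no array of a group have lower bounds, and those detected on some of its arrays have differences of uncertain size.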

Other observations

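The test of treated replicate 3 against treated replicates 1 and 2 is a description chosen only after the values were seen.

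Further gene lists held genes called in both directions after CHIRON, against dsRed2 negative cells. Over all 13204 genes 2651 were called higher and 2629 lower, so calls in both directions are not in themselves particular to a list. Camera called none of the lists below. Whether a list held more calls than other genes was not tested. Of 11 Nodal/Activin targets 5 rose and 4 fell, with Fst at 3.82 (camera adjusted p = 0.49). Of 11 FGF/ERK targets 4 rose and 2 fell, with Spry4 at 1.38 and Etv5 at −1.38 (adjusted p = 0.599). Of 6 Notch targets 4 rose and 1 fell, with Hes1 at 1.05 and Dtx4 at −1.11 (adjusted p = 0.223). Of 12 primed epiblast genes 5 rose and 4 fell: Fgf5 rose by 1.83, and Sox3 was detected on 0 treated arrays and at least 1.87-fold lower (adjusted p = 0.984). Of 7 naive pluripotency genes 1 rose and 4 fell, with Esrrb at −1.80 (adjusted p = 0.251). Of 7 neural genes 2 rose, Irx3 by 3.23 and Sox21 from near background, detected on 1 negative array, and 1 fell (adjusted p = 0.469; median −0.17 and mean 0.93). Of 17 epithelial genes 4 rose and 5 fell, with Krt8 at 1.38 and Prss8 at −1.27 (adjusted p = 0.964), and of 3 surface ectoderm genes 1 rose, Grhl3 at 0.81, and 1 fell (adjusted p = 0.964). Over each list alone the counts were the same, except 2 naive genes that rose, 5 primed genes that fell, and 5 epithelial genes that rose and 6 that fell.

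Of 9 visceral and parietal endoderm genes 3 rose and 1 fell, with Apoa1 at least 9.02-fold and Apoe 4.01-fold lower (adjusted p = 0.0519). Of 7 fibroblast and feeder genes 2 rose, Col1a1 by 2.55 and Col6a1 by 1.62, and Thy1 fell by 2.40 (adjusted p = 0.311). Of 3 endothelial and blood genes 2 rose, Flt1 by 3.57 (adjusted p = 0.0759). Of 10 heat shock genes 3 rose, Bag3 by 1.17, and 2 fell (adjusted p = 0.703). Of 11 p53 response genes 2 rose, Cdkn1a by 1.03, and 2 fell, Bbc3 by 1.52 (adjusted p = 0.57). Of 14 cholesterol synthesis genes 1 rose and 5 fell, Mvd by 1.11 (adjusted p = 0.0759). Of 9 housekeeping genes 2 fell, Hprt by 2.29 and Pgk1 by 0.89, and 0 rose (adjusted p = 0.318); the value of Pgk1 was −0.58 without treated replicate 3. Over each list alone the counts were the same, except 4 endoderm genes that rose.

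Treated replicate 3 stood apart from treated replicates 1 and 2 in named genes, chosen after their values were seen. Acta2 was at 12.9 on it against 10.2 on each of the other treated arrays, Tagln at 8.09 against 5.61 and 5.72, the posterior gene Evx1 at 9.44 against 7.50 and 7.46, and Hoxc9 at 7.54 against 5.11 and 5.29. Chrd, which encodes the BMP antagonist chordin, was at 7.11 against 8.90 and 8.74, and Tbx6 at 5.15 against 7.30 and 7.28.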
